A study of Lactiplantibacillus plantarum with 6 samples.

How the data were processed

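Total RNA from cultures of 3 Lactiplantibacillus plantarum strains was converted to cDNA, coupled to Cy3 or Cy5 and hybridised in pairs to custom 60-mer arrays, per the labels. Per the series text, slides were scanned with ScanArray Express, and per the file headers, spots were quantified with ImaGene 5.6.0. The deposited scanner files give the mean intensity of each spot and of its local background for 1 dye, neither background-corrected nor normalised. The deposited table of the series holds log2 ratios per spot that the authors made by background correction on mean values and lowess normalisation, per the deposited protocol. It covers 9607 of 10807 spots. Its scale, centring and direction were found by setting it against the scanner files: the slope on log2(Cy5/Cy3) was -0.983 to -0.930, the column medians were -0.035 to 0.0081, and the sign was opposite to Cy5 over Cy3. The series text names limma, an adjusted false discovery rate under 10% and 1.5-fold for the authors' own testing.

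The main values were made from the deposited intensities. Background was corrected with normexp and an offset of 50, ratios were normalised within arrays by loess with control spots at weight 0, and average intensities were quantile-normalised between arrays over gene spots, all in limma 3.58.1 under R 4.3.3. Each channel's level was then the average intensity plus or minus one part in 2 of the log ratio. Spots of a probe were averaged, and a gene's value is the mean over its probes, with the SD over probes as its error. A probe entered when its signal exceeded the local background by 2 background SDs in at least 0.5 of its measurements, which kept 7938 of 7968 probes. Genes with at least 2 probes were compared, 2667 in all. The highest mean signal of a spot was 31443, and no such mean was at the ceiling of the scanner. Saturated pixels within a spot were not examined. Spots marked as poor by the quantification software were kept: the mark fell on 90.0% of 1209 spots above a log2 signal of 13 and on 2.2% of the rest, so leaving them out removes the brightest genes. Spots of the array's own controls and other probes without a locus tag were left out of the comparisons. Figures were drawn with matplotlib 3.10.9.

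Before the data were examined, the groups, the gene lists, the 1.5-fold threshold, a limma model over all 6 arrays and the alternatives had been fixed. That model could not stand once 2 pairs of arrays proved to be the same hybridizations, since the 4 hybridizations leave no residual degrees of freedom for strain, aeration and dye terms. It was run on the 6 arrays as labelled, counting each scan as an array, only as a check. Its 2 residual degrees of freedom then rest on repeated scans, and its aeration coefficient correlated at r = 0.982 with the difference between the 2 unpaired arrays. No gene or list is therefore called by a test, the counts from that check are given only with the alternatives, and the planned comparisons of anaerobic RNAs of the mutants were not made. The merging of arrays, the rule of 2 readings and the dye difference taken from 1 RNA in both dyes, in place of that from the loop of aerobic arrays, were chosen after the data were seen.

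Aeration in WCFS1 was read as the ratio within its array and as that ratio less the dye difference, which is aerobic NZ7603 RNA in Cy5 on one array minus the same RNA in Cy3 on another. NZ7603 over WCFS1 was read as the ratio within its array and as the Cy5 level of NZ7603 minus the mean of the 2 Cy5 levels of WCFS1. NZ7608 over WCFS1 and NZ7603 over NZ7608 were read in Cy5 against Cy5 and as the ratio within the array under the label that names both strains as aerobic. A gene counted as higher or lower when at least 2 probes all had the same sign and the mean passed 1.5-fold in both readings. The 2 readings of a comparison are not independent. Those of aeration share an array, and those of NZ7603 over WCFS1 share a WCFS1 Cy5 channel. Both readings of NZ7608 over WCFS1 use the same NZ7608 Cy5 channel, and both of NZ7603 over NZ7608 the same NZ7603 Cy5 channel. The rule for named genes, fixed beforehand for comparisons with no test, gives the 5 highest and 5 lowest genes, narrowed after the data were seen to those that passed and ranked by the mean of both readings, up to 4 members of each list with the largest differences, and every member of the lists for thioredoxin, peroxide and pyruvate oxidase genes. Other genes, among them lp_0889, were chosen after their values were seen. Levels of different probes were not compared with each other.

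Of 25 gene lists fixed by symbol, 19 had a member and 12 had at least 4. A list holds only genes with a known symbol, so its counts do not cover a whole pathway. Lists for thioredoxin, glutathione, iron-sulfur assembly, prophage, surface polysaccharide and phosphotransferase genes had no member with a known symbol. Symbols came from the platform table, which names 334 symbols on 337 loci. A symbol on 2 loci was replaced by the tags. The reference gene table belongs to another strain and was not used here. A list median was placed among 10000 random lists of equal size, matched on mean intensity in 10 bins, as a description of these arrays and not a test.

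The steps were tested on simulated data of 2669 genes with known differences. For aeration 78.7% of genes changed by 2-fold and 93.2% of those changed by 3-fold were recovered, for NZ7603 81.0% and 95.2%, and for NZ7608 83.1% and 98.3%, and no unchanged gene passed. Of 200 random lists 6% fell outside the central 95% range. The number of arrays limits the precision, and the simulation leaves out differences between cultures. It also gave every array the same dye effect, with noise within an array that was small beside the 1.5-fold threshold. That no unchanged gene passed follows from these settings and gives no error rate for the real arrays. Alternatives covered background correction, normalisation, the value per gene, the dim-probe filter, the authors' log ratios, the dye term, the fold threshold and single readings, and those added later left out the marked spots, 1 scan of each pair or 1 WCFS1 measurement.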

Results

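Lactiplantibacillus plantarum is a lactic acid bacterium of plant material and fermented food that can grow with or without air. Total RNA of 3 strains was compared on 2-colour oligonucleotide arrays. WCFS1 is the wild type. In NZ7608 and NZ7603 a chloramphenicol resistance marker interrupts trxB1 and trxB2, respectively, genes named for thioredoxin reductase, the enzyme that passes electrons from NADPH to thioredoxin. Per the labels, each strain was grown aerobically and anaerobically, which gave 6 RNAs, 1 for each strain and condition, and 6 arrays. The arrays carried 7968 probes for 2851 loci, with a mean of 2.79 probes per locus. The tables used here pair neither trxB1 nor trxB2 with a locus tag, so the levels of the disrupted genes were not analysed here, and gene symbols were known for 337 loci. All other loci are named by tag.

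The spots were well measured, but the 6 arrays did not hold 6 hybridizations. The median signal above background lay between 376 and 646 units over the 12 channels, and 98.7% to 99.9% of the gene spots exceeded background in a channel. The array labelled NZ7608 over WCFS1, both aerobic, and the array labelled NZ7608 aerobic over anaerobic had log ratios that correlated across spots at r of 0.982 or more, as did the arrays labelled NZ7603 over NZ7608, both aerobic, and NZ7603 aerobic over anaerobic. The other 13 pairs of arrays reached r values of 0.309 to 0.675. Between replicate spots of the same probe, where no biological difference exists, the difference of the log ratio correlated at 0.712 to 0.716 within the 2 pairs and at 0.122 to 0.285 between other arrays. Each of the 2 pairs was therefore averaged and counted as 1 hybridization. The labels of a pair name the same aerobic mutant RNA in Cy5 and different RNAs in Cy3.

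**Figure D1:**
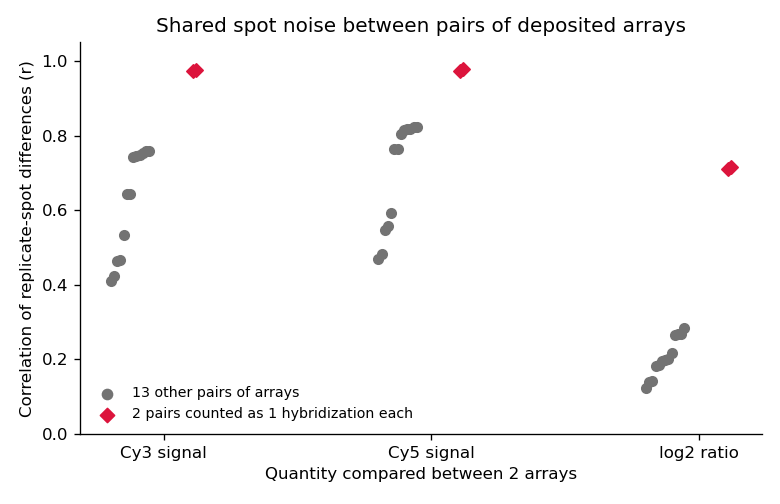
Correlation (r, vertical axis) between 2 arrays of the difference between replicate spots of a probe, over 822 probes with 2 spots, for the Cy3 signal, the Cy5 signal and the log2 ratio. Each point is 1 pair of arrays: the 2 pairs counted as 1 hybridization each lie at 0.973 or more for both dyes, and the 13 other pairs at 0.824 or less.

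The 4 hybridizations left 1 wild-type aeration comparison and the aerobic strain comparisons. Aerobic WCFS1 RNA was in Cy5 on 2 arrays, once against its anaerobic RNA and once against aerobic NZ7603 RNA. These 2 Cy5 measurements of the same RNA differed with an SD of 0.156 (log2) over 2667 genes, and 1 gene was at least 1.5-fold higher and 2 were lower. With 1 RNA per strain and condition no difference has a replicate check and no p-value is given. Errors are SDs over the probes of a gene, which measure technical spread only. Each comparison was read in 2 ways, and a gene counts as higher or lower where at least 2 probes all shared the direction and the mean was at least 1.5-fold in both readings. The 2 readings share a channel, so a deviation in that channel can move both. Positive log2 values mean more RNA in the sample named first. The deposited table of log ratios runs in the opposite sense to the Cy5 over Cy3 ratios of its own scanner files, with r between -0.993 and -0.970, and the directions given here follow the dyes in the labels and scanner files.

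The first comparison asks which WCFS1 genes differ in RNA level between aerobic and anaerobic growth. The gene with the largest difference was lp_2629, at a log2 ratio of 3.60 ± 0.62 (SD, n = 3 probes), a 12.2-fold higher level with air. It was followed by lp_1836 at 2.39 ± 0.14, lp_1360 at 2.26 ± 0.43, lp_3578 at 2.24 ± 0.16, lp_0889 at 2.22 ± 0.31 and lp_2113 at 2.05 ± 0.81, each over 3 probes. The gene nrdD, which encodes the oxygen-sensitive ribonucleotide reductase used without air, had the lowest value of all genes at -1.39 ± 0.12, and nrdG, which encodes its activating enzyme, stood at -1.01 ± 0.27. The neighbouring tags lp_3103 and lp_3105 had values of -1.04 ± 0.38 and -1.02 ± 0.08, and lp_1070 had -1.05 ± 0.11. The dye difference, taken from aerobic NZ7603 RNA that was measured in both dyes, was then subtracted, and these values became 3.79 ± 0.13 for lp_2629, 2.56 ± 0.06 for lp_1836, 2.13 ± 0.27 for lp_1360, 1.83 ± 0.18 for lp_3578, 1.72 ± 0.26 for lp_0889, 2.31 ± 0.93 for lp_2113, -1.23 ± 0.13 for nrdD and -0.64 ± 0.29 for nrdG. The lowest dye-corrected value that passed was -1.24 ± 0.25, of lp_3104 beside lp_3103.

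In both readings 62 of 2667 genes were higher and 10 were lower with air, and 18 and 3 of them passed 2-fold. The 2 readings correlated across genes at r = 0.706, although they share the same array and genes are not independent replicates. The ratio alone gave 88 higher and 16 lower genes, and the dye-corrected reading alone 145 and 20. With the dye difference from the loop of aerobic arrays the counts were 52 and 11, and without background subtraction 31 and 2. Strain differences cancel over that loop only if the contradicted Cy3 labels that name aerobic strains are right.

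**Figure D2:**
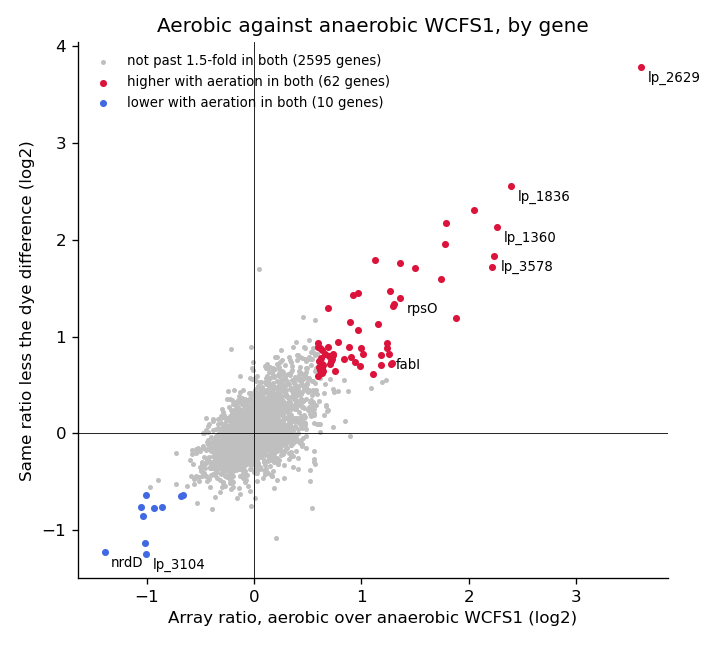
Log2 difference of each of 2667 genes between aerobic and anaerobic WCFS1, as the array ratio (horizontal axis) and as the same ratio less the dye difference (vertical axis). Each point is a gene: 62 were higher (red) and 10 lower (blue) by at least 1.5-fold in both, with lp_2629 at 3.60 and 3.79 and nrdD at -1.39 and -1.23.

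Of the 4 fatty acid biosynthesis genes with a known symbol and at least 2 probes, 2 were higher with air and 2 did not pass. The gene fabI, encoding enoyl-acyl carrier protein reductase, was higher at 1.26 ± 0.18 and 0.82 ± 0.12 (n = 3 probes), and fabF, encoding a ketoacyl synthase of chain elongation, was higher at 1.02 ± 0.44 and 0.82 ± 0.12 (n = 3). The genes acpS and fabG, which lie elsewhere and did not pass, had ratios of -0.08 ± 0.02 and 0.03 ± 0.03, and -0.51 ± 0.22 and -0.30 ± 0.30 after dye correction. The list median was 0.52, above 98.1% of random lists of equal size and intensity, and after dye correction it was 0.26, above 76.2%. The tags next to fabF and fabI, from lp_1670 to lp_1682, were chosen after their values were seen. They held 12 genes with a median of 1.19, or 2.27-fold, and a dye-corrected median of 0.71, or 1.63-fold, and 9 of the 12 were higher in both readings. With the dye difference from the loop of aerobic arrays, which had been set beforehand, the median was 0.58, or 1.49-fold, and 6 of these 9 genes still reached 1.5-fold. These loop values depend on the contradicted Cy3 labels that name aerobic strains. The stretch is among the brightest on the arrays, where 90.0% of spots above a log2 signal of 13 were marked as poor, and without the marked spots no dye-corrected median could be had.

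Among 44 ribosomal protein genes 3 were higher and 41 did not pass. They were rpsO at 1.36 ± 0.05 and 1.40 ± 0.34 (n = 2 probes), rplS at 0.97 ± 0.12 and 1.45 ± 0.02 (n = 3) and rpsP at 0.76 ± 0.12 and 0.65 ± 0.41 (n = 3). The list median gave no stable position, being 0.19 and above 98.5% of random lists as a ratio, and 0.04 and above 4.74% after dye correction. Outside the list, 2 more genes of protein synthesis were higher, tuf, encoding elongation factor Tu, at 0.62 ± 0.39 and 0.78 ± 0.33, and frr, encoding the ribosome recycling factor, at 0.70 ± 0.52 and 0.80 ± 0.58. Both were picked after their values were seen.

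The citrate genes had lower values with air, although no single member passed 1.5-fold in both readings. All 5 members were below 0, with a median of -0.47, lower than every one of 10000 random lists, and of -0.32 after dye correction, above 0.93% of them. The members citC, citD, citE and citF carry the consecutive tags lp_1106 to lp_1109. Neighbouring genes may move together, whereas random lists draw scattered genes. The percentiles of this list, here and in the mutants, may therefore overstate how unusual it is. The subunits of citrate lyase had -0.57 ± 0.04 and, after dye correction, -0.32 ± 0.15 for citE (n = 3 probes), -0.47 ± 0.14 and -0.42 ± 0.18 for citF (n = 3), and -0.46 ± 0.04 and -0.24 ± 0.14 for citD (n = 2). The gene citC, encoding the ligase that activates the enzyme, had -0.48 ± 0.12 and -0.44 ± 0.12 (n = 3). The 9 respiratory and nitrate genes had medians of -0.12 and -0.15, above 9.91% and 3.32% of random lists, and cydC, of an export system for cytochrome assembly, had -0.35 ± 0.15 and -0.28 ± 0.20.

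Of 10 chaperone and protease genes clpP, encoding the proteolytic subunit of Clp protease, was higher at 0.64 ± 0.21 and 0.86 ± 0.21, and clpL, encoding a Clp ATPase, was lower at -0.66 ± 0.28 and -0.64 ± 0.32, with medians of -0.03 and 0.16 over the list. The alkaline shock gene asp1 was lower at -0.85 ± 0.02 and -0.76 ± 0.41. Of the 5 ribonucleotide reductase genes nrdD and nrdG were lower and the other 3 did not pass, among them nrdF at 0.40 ± 0.17 and 0.29 ± 0.19, and the list medians were 0.38, above 97.2% of random lists, and -0.05, above 19.8%. The thiol peroxidase gene tpx, the 1 member of the peroxide list with a known symbol and at least 2 probes, had 0.52 ± 0.08 and 0.19 ± 0.41. The SOS gene lexA had 0.73 ± 0.11 as a ratio and 0.06 ± 0.27 after dye correction, and recA had 0.35 ± 0.08 and 0.66 ± 0.08, and none of the 8 genes of that list passed, with medians of 0.14 and 0.12.

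None of the 5 glycolysis genes passed, with medians of -0.05 and -0.07, although fba, encoding fructose-bisphosphate aldolase, had 0.46 ± 0.27 as a ratio and 1.20 ± 0.05 after correction. The pyruvate genes pdhA and pta had ratios of -0.19 ± 0.16 and -0.04 ± 0.14, and -0.18 ± 0.35 and 0.37 ± 0.29 after correction. The alcohol and acetaldehyde dehydrogenase gene adhE had -0.45 ± 0.22 and -0.45 ± 0.10. None passed among 14 purine genes with medians of 0.05 and 0.03, 6 arginine genes with -0.04 and -0.07, 4 cysteine and methionine genes with 0.02 and 0.06, and 5 ATP synthase genes with -0.08 and 0.03. The iron transporter gene feoB stood at -0.03 ± 0.04 and -0.17 ± 0.10, and the 3 pyrimidine genes had medians of -0.20 and -0.15.

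**Figure D3:**
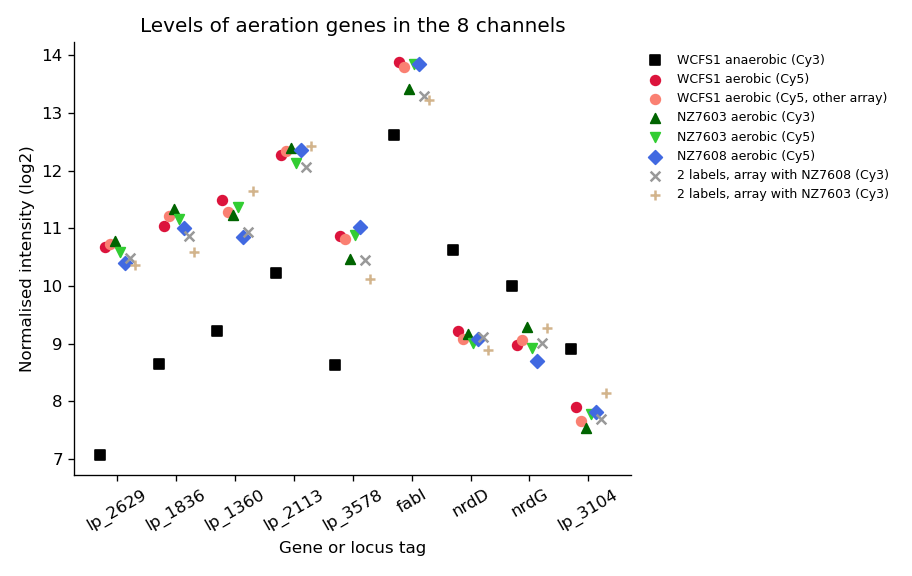
Normalised log2 intensity of 9 genes in the 8 channels of the 4 hybridizations, with 1 symbol per channel. Anaerobic WCFS1 (black squares) stood apart from the aerobic RNAs of all 3 strains, at 7.06 against 10.40 to 10.77 for lp_2629 and at 10.62 for nrdD, and the Cy3 RNAs with 2 labels (crosses) lay near the aerobic ones.

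The next comparison asks how aerobic NZ7603, the trxB2 mutant, differs from aerobic WCFS1. Here 22 genes were higher and 1 was lower of 2667, and 15 of the 22 lay between the tags lp_0403 and lp_0431, a stretch that carries the plantaricin genes plnE, plnF and plnJ. Plantaricins are peptide bacteriocins that act against related bacteria. The largest difference was that of lp_0416, at 5.06 ± 0.14 (SD, n = 3 probes), or 33.3-fold, within the array and 4.02 ± 0.32 with both RNAs in Cy5. The next were lp_0423 at 3.73 ± 0.24 and 3.28 ± 0.15, lp_3248 at 3.25 ± 0.29 and 2.81 ± 0.14 (n = 2), lp_0404 at 2.98 ± 0.25 and 2.58 ± 0.19, and lp_0424 at 2.63 ± 1.00 and 2.44 ± 0.89. For plnJ the values were 2.53 ± 1.21 and 2.36 ± 1.00 (n = 2), and the single probes of plnE and plnF gave 2.95 and 2.56 within the array and 3.14 and 2.68 in Cy5.

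The stretch was examined because its genes led the ranking. All 15 of its genes with at least 2 probes were higher in NZ7603, with medians of 2.35 within the array, 5.12-fold, and 2.14 in Cy5, 4.42-fold. The same genes had a median of -0.04 between the 2 measurements of the same WCFS1 RNA, and of -0.22 and 0.04 with aeration in WCFS1. Elsewhere lp_3246, near lp_3248, was higher at 1.43 ± 0.24 and 1.63 ± 0.11, and lp_1230 was higher at 1.04 ± 0.02 and 0.70 ± 0.22. The 1 lower locus was lp_RNA02, at -0.85 ± 0.57 and -1.19 ± 0.22 (n = 3), and without the spots marked as poor no locus was lower. Within the array alone 50 genes were higher and 51 lower.

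No list member outside plantaricin passed in NZ7603. The 5 citrate genes were all below 0, with medians of -0.30 within the array and -0.39 in Cy5, above 2.23% and 0% of random lists, and citC stood at -0.37 ± 0.07 and -0.39 ± 0.04 and citE at -0.30 ± 0.13 and -0.49 ± 0.02. Ribosomal protein genes differed between the readings, with a median of -0.16 within the array, above 0.05% of random lists, and of -0.10 in Cy5, above 36.6%. Thus rplB had -1.29 ± 0.13 and 0.01 ± 0.16, and rplD had -1.07 ± 0.42 and -0.02 ± 0.13. The 10 chaperone genes had medians of 0.17 and -0.03 and the 4 fatty acid genes had -0.34 within the array, above 2.11% of random lists, and lay above 83.2% in Cy5, with fabF at -0.32 ± 0.28 and, in Cy5, -0.01 ± 0.04. The thiol peroxidase gene tpx had -0.16 ± 0.30 and 0.10 ± 0.11, and clpL had 0.25 ± 0.29 and 0.11 ± 0.06.

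For aerobic NZ7608, the trxB1 mutant, the plantaricin stretch again held the largest differences. With both RNAs in Cy5, lp_0416 was higher by 4.35 ± 0.36 (SD, n = 3 probes), or 20.4-fold, lp_0423 by 3.97 ± 0.22, lp_0404 by 3.26 ± 0.17, lp_0419 by 3.19 ± 0.19 and lp_0428 by 2.86 ± 0.07. Under the label that pairs the array with WCFS1, the ratio within the array gave 5.16 ± 0.30, 3.65 ± 0.83, 3.20 ± 0.38, 3.33 ± 0.21 and 2.75 ± 0.01 for these genes. The genes plnJ, plnE and plnF had Cy5 differences of 2.69 ± 1.16 (n = 2), 4.45 and 3.87, the last 2 from single probes. Within the array plnJ had 1.92 ± 2.20, an SD above the mean, and plnE and plnF had 4.40 and 3.47. All 15 genes of the stretch were higher, with medians of 2.69 in Cy5, 6.46-fold, and 2.37 within the array, 5.19-fold.

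Of 2667 genes 24 were higher and 1 lower in NZ7608 in both readings. Beyond the stretch, lp_3248 had 2.76 ± 0.26 in Cy5 and lp_3246 had 1.87 ± 0.22, and the plasmid tags lp_p1_01 and lp_p2_01 were higher at 1.35 ± 0.12 and 0.59 ± 0.40. Within the array these 4 had 2.81 ± 0.75, 2.36 ± 0.29, 0.96 ± 0.63 and 1.12 ± 0.30. The lower gene was lp_0694, at -1.04 ± 0.19 and -0.73 ± 0.08 (n = 2). The within-array reading rests on 1 of 2 contradictory labels, and the Cy5 reading compares different slides. Alone they gave 82 higher and 10 lower, and 30 higher and 15 lower.

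In NZ7608 no list member outside plantaricin passed. The citrate median was -0.21 in Cy5, above 2.1% of random lists, and -0.14 within the array, above 28.4%. Ribosomal protein genes had a median of -0.14 in Cy5, above 0.7%, with rplQ at -0.54 ± 0.16 (n = 2) and rpsB at -0.31 ± 0.08, and within the array -0.74 ± 0.03 and -0.57 ± 0.24. The within-array median of -0.10, above 2.22%, became 0.049 under median centring. The respiratory and nitrate genes had medians of -0.10 and -0.29, above 7.57% and 0.1%, with moaA at -0.25 ± 0.14 and -0.48 ± 0.32. Among the chaperone genes grpE had 0.39 ± 0.06 and 0.26 ± 0.08, and clpP had -0.50 ± 0.28 and -0.10 ± 0.07. The thiol peroxidase gene tpx had -0.25 ± 0.25 and 0.04 ± 0.19.

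The mutants shared 17 higher genes and no lower gene, and no gene was higher in one and lower in the other. These 17 were the 15 genes of the stretch with lp_3246 and lp_3248. Independent lists of 22 and 24 genes would share 0.198 genes by chance, but these lists rest on the same aerobic WCFS1 RNA. In 100 simulations of unchanged strains set against the shared WCFS1 values, which hold measurement noise and no difference between cultures, no gene was higher in both. Their noise was set from SDs over genes of 0.156 in Cy5 and 0.374 in Cy3, without gene-specific dye differences. With such noise a gene could hardly pass 1.5-fold in every reading, so this count adds no support to the overlap. A feature of the 1 aerobic WCFS1 culture would appear in both mutants. In the stretch, however, anaerobic WCFS1 RNA was near the aerobic one, with aeration medians of -0.22 and 0.04. The low level was thus not confined to the aerobic WCFS1 RNA.

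Between the mutants, 2 genes were higher and 4 lower in NZ7603 than in NZ7608. The neighbours lp_1230 and lp_1229 were higher in NZ7603, at 1.00 ± 0.29 and 0.59 ± 0.54 (n = 3 probes) in Cy5 and 0.78 ± 0.16 and 1.08 ± 0.31 within the array. Lower were lp_RNA02 at -1.26 ± 0.35 and -2.78 ± 0.14, lp_p1_01 at -0.99 ± 0.23 and -0.63 ± 0.44, lp_2061 at -0.87 ± 0.25 and -0.62 ± 0.08, and lp_3129 at -0.81 ± 0.09 and -0.64 ± 0.48 (n = 2). The plantaricin stretch had medians of -0.49 in Cy5 and -0.12 within the array, and none of its 15 genes passed. In Cy5 the respiratory and nitrate list had a median of 0.18, above 99.9% of random lists, and within the array -0.26, above 12.5%. The SOS list had 0.14, above 99.1%, and 0.21 within the array, above 73.3%, with lexA at 0.37 ± 0.08 and 0.99 ± 0.15. The glycolysis list had -0.19, above 5.85%, and -0.54, above 1.16%, with fba at -0.42 ± 0.16 and -1.38 ± 0.37. Across genes the 2 readings did not rise together, with r of -0.058. Alone, the Cy5 reading gave 7 higher and 19 lower genes, and the within-array reading 200 and 206. The number expected to pass both by chance was not computed, so the genes named here are not shown to exceed it. The within-array reading also rests on the label that names both strains as aerobic, which the other label of that array contradicts.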

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

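All tests in this part were chosen after the results were seen.

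Probes outside the gene set gave signal above the negative-control spots. The 99th percentile of 89 negative-control spots was exceeded in every one of the 12 channels by 35 of 36 probes named mtf, by 3 of 3 probes named as antisense to a locus and by 4 of 4 probes named THI, RFN or SRP. These probes entered none of the comparisons, and what the names stand for is not given in the sources used here.

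The first pattern is the near identity of 2 pairs of arrays. Separate hybridizations of the same RNAs would draw spot noise anew, yet the Cy3 difference between replicate spots correlated at 0.974 or more within the pairs, against at most 0.760 between other arrays. A second scan of the same array may explain the pairs: the replicate-spot difference of the log ratio correlated at 0.712 or more, against at most 0.285. No biological explanation was tested.

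The next pattern is the contradiction in the labels of these arrays, whose Cy3 RNA is named as aerobic by one label and as anaerobic by the other. Over 104 genes past 1.5-fold on the WCFS1 aeration array, the Cy3 RNA of the array with NZ7608 in Cy5 was shifted toward the anaerobic WCFS1 level by 17.9% of its shift (bootstrap interval over genes 9.39 to 25.1), and that of the array with NZ7603 in Cy5 by 12.1% (-2.78 to 24.4). Both intervals lie under the 50% set as the limit, although 74 and 61 of the 104 genes lay toward the anaerobic level and the former interval excludes 0. The genes were picked on the same anaerobic WCFS1 channel that gives the reference shift. That choice enlarges the reference and lowers both percentages by an amount not measured, and the intervals cover genes, not RNAs. The values therefore argue only weakly against an anaerobic RNA with the full aeration response of WCFS1 in either channel. An anaerobic mutant RNA with a weak response or, beside NZ7603, with none stays open, since no other array holds such an RNA. Which label is right stays open too. For the 15 genes of the plantaricin stretch the median level relative to aerobic NZ7603 in Cy3 was -1.96 for the Cy3 RNA beside NZ7608 and -0.08 for that beside NZ7603, while anaerobic WCFS1 had -2.00. Aerobic NZ7608 in Cy5 was higher than the Cy3 RNA beside it by a median of 2.37 over these genes. An anaerobic NZ7608 RNA with no response would share the high level, so these genes argue against it in that channel. One that responded in this stretch stays open.

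The last pattern is the higher plantaricin stretch in both mutants. A difference between slides would vanish within 1 array, where the NZ7603 median was 2.35. A dye bias would vanish between Cy5 channels, where the NZ7608 median was 2.69. The genes stood out because they passed 1.5-fold in both kinds of reading. Medians above that limit were therefore fixed beforehand and are no separate test of either explanation. Dyes exchanged throughout would turn the direction, but the 2 Cy5 channels named as the same RNA differed with an SD of 0.156 over genes and the 2 Cy3 channels named as different RNAs with 0.374. Cy5 levels named as different RNAs also differed less than this Cy3 value. The SD was 0.196 between the mutants, and 0.262 for NZ7603 and 0.304 for NZ7608 against WCFS1. The comparison of SDs thus mixes RNA with dye and does not decide by itself. As a hypothesis, the difference may lie in the RNAs, through the lost reductases or through the cultures. Each strain gave 1 aerobic RNA, and both mutants were set against that of WCFS1, so mutation and culture stay open as untested. The low level in WCFS1 was not confined to its aerobic RNA, as the stretch had aeration medians of -0.22 and 0.04.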

How the results depend on the processing

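The single scans, single WCFS1 measurements, marked spots, single Cy5 readings and the fit on the arrays as labelled, counting each scan, were chosen after the results were seen, and the other settings before. Of 118 recomputed gene counts 42 moved by more than 1.5 times, and of 1058 list medians 67 moved by more than the SD of random lists. The sign changed for 55 of these medians, in 36 of 96 lists and readings, so the direction of many list medians depends on the settings. Among lists outside the central 95% of random lists 1 changed sign, the ribosomal protein list of NZ7608 within the array, at 0.049 under median centring. The lp_0403 to lp_0431 medians stayed above 0 in all 48 recomputations. All were lowest without background subtraction, at 1.26 in Cy5 and 1.40 within the array for NZ7603 and at 1.67 and 1.58 for NZ7608, and of these the Cy5 medians moved by more than the SD over the genes of the stretch. Under median centring the lp_1670 to lp_1682 median was 1.49 as a ratio and 0.45 after dye correction, the latter below 1.5-fold. No named gene that passed changed sign, although 151 of 5771 values of named genes did, and 426 moved by more than their SD over probes.

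Counts that moved are given as higher and lower genes. Without background subtraction aeration had 31 and 2, NZ7603 over NZ7608 had 0 and 1, and NZ7608 had 0 lower. Plain subtraction gave 16 lower for aeration, 10 for NZ7603 over NZ7608, 2 for NZ7603 and 3 for NZ7608. Median centring gave 2 lower for NZ7603 and for NZ7608, and 3 and 2 between the mutants in place of 2 and 4. The authors' log ratios gave 16 lower for aeration and 2 for NZ7608, and no dye term gave 16 lower for aeration. At 2-fold aeration had 18 and 3, NZ7608 15 and 0, NZ7603 0 lower, and NZ7603 over NZ7608 0 and 1, as the stricter threshold requires. Ratios within single arrays gave 50 and 51 for NZ7603, 82 and 10 for NZ7608, and 200 and 206 between the mutants. Paths over the third strain, which add up dye differences, gave 408 and 397, 416 and 417, and 263 and 360. Cy5 channels alone gave 4 lower for NZ7603, 15 lower for NZ7608, and 7 and 19 between the mutants. Without marked spots NZ7603 had 0 lower and 1 was higher over NZ7608, and with the scan labelled as aerobic and anaerobic 1 was higher over NZ7608. With WCFS1 from 1 array, NZ7608 had 1 to 2 lower. Apart from the stricter threshold and the added dye differences, the cause was not tested.

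The fits with an intensity trend, a loop fit, array-level strain fits, camera and left-out arrays were not run, as they need residual degrees of freedom. No mean spot signal was at the ceiling of the scanner, but saturated pixels within spots were not examined. Without marked spots no dye-corrected lp_1670 to lp_1682 median could be had. The limma fit on the arrays as labelled gave 0 genes for aeration and both mutants, with 1, 27 and 33 genes at an unadjusted p under 0.05, and 79, 19 and 20 without the dye term. No paired analysis was possible because each group holds 1 array. Although 98.7% or more of gene spots exceeded background, the median signal above it, 376 to 646 units, is close to the background of 481 to 483 units. Values of dim genes may therefore depend on how background is handled, which was not tested by brightness.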

Other observations

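The runs and the plasmid values of this part were chosen after the results were seen. Genes that differed lay next to each other on the chromosome more often than shuffled positions gave. Of 70 chromosomal genes that differed with aeration, 18 lay in 5 runs of neighbours with the same direction, against a mean of 2.75 and at most 10 in 1000 shuffles. The longest ran from lp_1674 to lp_1682 with 8 genes and a median log2 of 1.19. The run lp_3103 to lp_3106 had 4 genes with a median of -1.01, nrdG and nrdD formed a run with -1.20, lp_2610 to lp_2612 one with 1.56, and lp_0836 to lp_0837 one with 1.01.

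In both mutants 15 genes from lp_0404 to lp_0431 formed a single run, against at most 6 genes in runs after shuffling. Within it the values differed by gene. The tag lp_0413 had the smallest difference, 0.94 within the array and 0.71 in Cy5 for NZ7603, and lp_0431 had 1.23 and 0.76, whereas lp_0416 had 5.06 and 4.02. The genes plnE and plnF were higher in NZ7608 than in NZ7603 in Cy5, at -1.31 and -1.19 for NZ7603 over NZ7608, but stood at 0.04 and -0.37 within the array, each from 1 probe.

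The 37 plasmid genes had a median of 0.25 in Cy5 and 0.30 within the array for NZ7608 over WCFS1, with 2 higher genes, and of -0.03 in Cy5 and 0.02 within the array for NZ7603 over WCFS1. For NZ7603 over NZ7608 the median was -0.30 in Cy5 but 0.01 within the array, so a difference between the mutants was not seen in both readings. Both NZ7608 readings share the same Cy5 channel, and the within-array readings of NZ7608 rest on contradicted Cy3 labels. With aeration in WCFS1 they had -0.12, and -0.11 after dye correction. The locus lp_RNA02 was higher with aeration in WCFS1, at 1.79 and 2.18, and lower in NZ7603 than in NZ7608 by -1.26 and -2.78. The value of -2.78 rests on a Cy3 RNA with a contradicted label. Its level was 15.0, against 13.5 for NZ7608 in Cy5.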
